A study of Mus musculus with 8 samples.

How the data were processed

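The series measured mRNA on 8 one-color mouse microarrays (Cy3), 1 array per group: p75NTR-positive, CD45-negative and Ter119-negative liver cells at E11.5, E13.5, E14.5, E17.5 and P1, adult HSC sorted by vitamin A, MEF and MSC. The liver cells were dissociated with collagenase and sorted by flow cytometry, per the labels. Whether animals were pooled for an array is not given in the sources used here.

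The intensity values in the scanner files are background-subtracted and spatially detrended spot signals that Agilent Feature Extraction 11.5.1.1 made, per the file headers, with no normalization between arrays. The authors' log2 values in the series table follow these signals divided by each array's 75th percentile and log-transformed, and they are not centered per gene (checked against the scanner files). The values computed here minus the authors' values had array medians from -0.103 (E11.5) to -0.150 (MSC). After that offset 93.2% of probes matched within 0.02 on the MSC array, 96.7% on the E14.5 array and 100% on the others. The column medians of the deposited log2 table lie between -4.48 and -3.55. The scanner files were used throughout and the series table as an alternative.

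Each value is the log2 processed signal minus the array's log2 75th percentile. Spots the scanner software marked as outliers were dropped, and spots of a probe were averaged. Probes were named through their transcript accession in a RefSeq gene table, which named 67.4% of the 39429 probes; the array's design rests on another genome build, so no positions were used. For a gene with more than 1 probe the probe with the highest mean over the 8 arrays was taken, and genes well above background on at least 1 array compared were tested. Among 249 cases of a named gene with more than 1 probe in a comparison, the probes differ in sign in 24, such as Igf1 and Fndc1 between liver-derived and other cells, Dlk1 and Meg3 from E11.5 to P1, and Col4a4 from P1 to adult HSC. In 3 cases another probe of the gene was above background where the taken probe was not (Ibsp, Nlrc5 from E11.5 to P1, Col4a6), and no bound is given for these. Folds come from the probe taken, and where another probe of the gene gives a much smaller difference the text gives the range for several of them. Listed genes with no named probe are not analysed here: Crabp2, Lama4, Rrm2, E2f1, H19, Hspa1b, Mx1, Serpina1b, Hbb-b1, Ahsp, Cd68, Muc16 and Bglap.

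Comparisons were 6 liver-derived arrays against the MEF and MSC arrays, a slope over the order of the 5 stages, P1 against E11.5, adult HSC against P1, and clustering of all arrays. The liver comparison and the slope used limma 3.58.1 in R 4.3.3 with Benjamini-Hochberg adjusted p under 0.05, and no array of these fits is a replicate of another, so the spread comes from arrays of different stages or cell types. The 2 pairs of arrays have no test: genes at least 4-fold apart were counted, a bound was given where 1 side was below background (the lowest signal well above background on that array; in the liver comparison also where only part of a side was below it), and list members at least 2-fold apart were counted. The lists, 21 in number, were fixed before the data were examined, as were the comparisons, thresholds, alternatives and the rule for naming genes. They were tested with limma's camera (preset correlation 0.01, and an estimated correlation), by adjusting p over the list alone, and, for the pairs, against 10000 random lists matched on expression. Clustering used all probes, named or not, well above background on at least 1 array.

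Genes were named by a rule: in each comparison the 10 highest and 10 lowest above background on every array compared (for the fits, only with adjusted p under 0.05, and for the slope only if also moving the same way at every step), up to 5 a side that were above background on all arrays of 1 side and none of the other, up to 4 members of each list with the largest change, and Ngfr, Lrat, Des, Acta2, Col1a1 and Tcf21. Some genes that the rule names are not reported here. Other genes named as members of a count of 5 or fewer (among them Angptl6, Pparg, Jun, Runx2, Tek, Hoxa2, Hoxa3, Hoxb4, Notch3, Timp1, Tpm1, Tpm2, and, over the stages, Adh1, Gfap, Gata4 and Hlx), and Hoxc6, were chosen after their values were seen.

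Each fit was tested on simulated data with 100 genes changed at each of 2 sizes. A slope of 1 per stage was recovered for 56% and of 2 for 86% (10 false calls over both sizes). A liver difference of 4 was recovered for 75% and of 8 for 91% (6 false calls over both sizes). The simulated noise was independent between genes and followed limma's own fitted variances, which the real arrays need not do. Alternatives were normexp background correction (offset 50, from median spot brightness), median and quantile normalization, no filter and a filter on all arrays, the mean of all probes, the authors' table, a floor at the lowest signal above background, slide as a block, only the 5 p75NTR-positive arrays as liver, leaving out each array, other fold thresholds and an estimated correlation. Slide 2 alone, a mean-variance trend with a robust prior, the bounds and the leave-outs for list shifts were added after the data were seen. The spike-in slope was 0.849 on the E11.5 array and between 0.922 and 0.933 on the others, and no correction was made for it. Probes with no gene name (12848) were left out of the comparisons.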

Results

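Gene expression was measured on 8 mouse microarrays with 1 array per group, so no group has a replicate and no spread between animals can be given. On 5 arrays the cells were p75NTR-positive liver cells at E11.5, E13.5, E14.5, E17.5 and postnatal day 1 (P1). The receptor p75NTR, encoded by Ngfr, binds nerve growth factor and marks hepatic stellate cells, the vitamin A-storing pericytes of the liver. These cells were taken from dissociated livers by flow cytometry as the fraction without CD45 and Ter119, surface markers of leukocytes and red cells. The remaining arrays held adult hepatic stellate cells (adult HSC, sorted by vitamin A), embryonic skin fibroblasts (MEF) and bone marrow mesenchymal stromal cells (MSC). Each array carried 43020 non-control spots, and 58.8% to 64.5% of them were well above background on an array, with 0 saturated spots. The 75th percentile of the signal lay between 243 and 414, and the number of arrays limits the precision of every value below. Of 39429 distinct probes, 26581 had a gene name, which gave 20062 genes, and 16442 of these were well above background on at least 1 array. The 4 fetal arrays share a slide and scan (slide 1), and the P1, adult HSC, MEF and MSC arrays share another (slide 2). Levels are log2 signals relative to the array's 75th percentile, and a level below background gives a fold only as a bound ("at least").

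The first question was which genes separate liver-derived cells (6 arrays) from mesenchymal cells of skin and bone marrow (2 arrays). Collectins and a set of transcription factors were higher in the liver-derived cells. Colec10 and Colec11, secreted collectins of innate immunity, were higher by at least 3925-fold for Colec10 and by 2309-fold for Colec11 (limma adjusted p = 0.00194 for each, log2 difference 11.17 ± 0.86 SE for Colec11). Gdf2, the ligand BMP9, was at least 3245-fold higher (limma adjusted p = 0.000191), and Nr1h5, a nuclear receptor, at least 1319-fold higher (adjusted p = 0.000183). Tcf21, a basic helix-loop-helix factor of visceral mesenchyme, was at least 255-fold higher (limma adjusted p = 0.0039). The study may have picked Tcf21 from these arrays, so its value is no independent evidence. For each gene given as higher or lower here, all 6 liver-derived arrays lay on the same side of both other arrays.

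By limma, 259 of 16442 genes differed at an adjusted p under 0.05, 139 higher and 120 lower in the liver-derived cells, with 3222 at an unadjusted p under 0.05. The groups did not overlap for 23.2% of genes, 2102 higher and 1720 lower. The average would be 7.14% if the 8 arrays were interchangeable. Genes can move together, so the spread around that average is unknown and the excess is not a test. The median of all genes was 0.02, and it moved to -0.35 with median normalization and to 0.35 with normexp. Of the 16 hepatic mesenchyme transcription factors measured, 8 were higher and 1 lower, and over the list alone 13 were higher and 1 lower ("adjusted over the list alone"). Lhx2, a LIM homeobox factor, was 347-fold higher, Gata4 at least 238-fold and Hand2 at least 143-fold, and the lower member was Pparg, a nuclear receptor of fat cells, by -3.53 ± 0.53 SE on the log2 scale. Of 18 stellate cell markers, 4 were higher (16 adjusted over the list alone): Colec10, Colec11, Reln at least 135-fold, and Angptl6 by 6.06. Ngfr itself was 118-fold higher at an adjusted p of 0.0961, Des, desmin, at least 21.9-fold at 0.133, and Lrat, which esterifies retinol, at least 101-fold at 0.138. Of 19 retinoid handling genes, 1 was higher (6 adjusted over the list alone): Rarb, a retinoic acid receptor, by 35.6-fold. Of 12 immediate early and stress genes, 4 were higher (9 adjusted over the list alone): Fosb 431-fold, Fos 86.6-fold, Hspa1a 39.2-fold, and Jun by 3.09 on the log2 scale. The liver cells were dissociated and sorted. Where the handling of MEF and MSC differed from that, tissue and handling cannot be told apart. Of 16 basement membrane genes, Lama1, a laminin chain, was higher by 257-fold, and 2 passed adjusted over the list alone.

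The lower side held positional genes. Of 38 Hox genes, 10 were lower and 3 higher (14 and 4 adjusted over the list alone). Those lower had paralog numbers from 6 to 13, such as Hoxc6 (16.5-fold), Hoxc9 (at least 357-fold), Hoxc10 (at least 63.0-fold) and Hoxa10 (at least 43.8-fold), and Hoxb9 was at least 265-fold lower, with only 1 of the 6 liver-derived arrays above background. No test of paralog number was run. The higher members were Hoxa2, Hoxa3 and Hoxb4, by 2.50, 1.68 and 2.34 on the log2 scale. The list's median of -1.65 turned to 0.06 with the normexp background correction and to 0.38 with genes above background on all arrays only. Of 22 skin, limb and skeletal transcription factors, 4 were lower (6 adjusted over the list alone): Tbx15 at least 120-fold, Foxd1 at least 34.6-fold, Shox2 at least 7.21-fold, and Runx2 at least 6.11-fold. Other genes lower in the liver-derived cells were S100a4, a calcium-binding protein of motile cells (489-fold), Fgf7 (48.7-fold), Trib3 (38.9-fold), Slco2a1, a prostaglandin transporter (35.6-fold), Tnfrsf23 (34.5-fold, log2 differences of its probes -5.11 and -2.77), F3, tissue factor (28.6-fold), Apol9a (by -4.32 on the log2 scale), Rin1 (19.6-fold) and Slc7a3, an amino acid transporter (18.6-fold). On the higher side stood also Rarres2, chemerin (248-fold), Rasgrp2 (223-fold), Adra2b, an adrenergic receptor (130-fold) and Acap1 (78.1-fold).

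Some markers of other liver cells were higher in the liver-derived cells and others were not. Of 15 endothelial markers, 3 were higher (8 adjusted over the list alone): Plvap, a protein of endothelial fenestrae, 394-fold (log2 differences of its probes 6.62 and 8.62), Clec4g at least 250-fold and Tek at least 5.48-fold. None of 14 hepatocyte and hepatoblast markers and none of 14 erythroid markers passed over all genes by limma (8 and 10 at an unadjusted p under 0.05), and these 8 and 10 were higher adjusted over the list alone. Alb was at least 606-fold higher at an adjusted p of 0.0892, Ambp, an alpha-1-microglobulin precursor of hepatocytes, at least 554-fold at 0.0707, and the globin Hba-a1 at least 527-fold at 0.159. Leukocyte and Kupffer cell markers had a median of -0.91, which turned to 0.08 with normexp (0 of 14 passed by limma, 1 at an unadjusted p under 0.05), and portal fibroblast (11) and mesothelial markers (9) gave 0 over the list alone as well (0 and 2 unadjusted). No member of the other 8 lists passed over all genes. Adjusted over the list alone, 3 of 24 myofibroblast and fibrosis genes were lower (Timp1, Tpm2 and Tpm1, the last with probes that differ in sign), and 2 of 14 hematopoietic niche factors (Cxcl12, Angpt1) and 3 of 10 smooth muscle and pericyte markers (Abcc9, Kcnj8, Notch3) were higher. Acta2 and Col1a1, smooth muscle actin and a collagen of scar, differed by -3.35 (limma adjusted p = 0.331) and -0.04 (adjusted p = 0.978).

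With limma's camera test and its preset correlation, 14 of the 21 lists shifted, and with an estimated correlation 0 did (estimated-correlation adjusted p = 0.056 for the hepatic mesenchyme transcription factors and 0.323 for the stellate cell markers). The lists that shifted upward at the preset value were stellate cell markers, retinoid handling, hepatic mesenchyme transcription factors, basement membrane, imprinted growth, immediate early and stress, hepatocyte, erythroid, endothelial and smooth muscle genes. Those that shifted downward were the skin, limb and skeletal factors, the Hox, the fibrosis and the cell cycle genes. With slide as a block 12 lists shifted, without the fibrosis (adjusted p = 0.369 by limma's camera) and imprinted growth lists (adjusted p = 0.520). In the same fit 74 genes passed (67 of them among the 259), and adjusted p was 0.00745 for Tcf21, 0.0214 for Lhx2, 0.0498 for Gata4 and 0.0105 for Colec11. Over all alternatives these adjusted p values ranged from 0.0028 to 0.361 for Tcf21, 0.00136 to 0.474 for Lhx2, 0.00119 to 0.506 for Gata4 and 0.00114 to 0.361 for Colec11, the highest within slide 2 alone. Within slide 2 alone, with 2 arrays a side, 0 genes passed by limma (1446 at an unadjusted p under 0.05), while the log2 differences stayed large: 12.06 against 11.17 for Colec11, 10.06 against 8.75 for Fosb and 8.25 against 8.44 for Lhx2. These arrays are part of those that picked the genes, so the sizes are no independent test. Without the MEF array 1277 genes passed, without the E17.5 array 82, without E14.5 89, without E13.5 93, without P1 167 and without the adult HSC array 524. Of the 259 genes, 59 passed in every run that left out 1 array. Of 37 genes that the naming rule gave and that passed, 12 passed in all alternatives but slide 2 alone, and 12 in fewer than 13 alternatives of 17 or 18. These were Rarb (12), Lama1, Rarres2, Fgf7 and Hand2 (10), Hspa1a, Adra2b, Apol9a and Rin1 (9), and Acap1, Slco2a1 and Clec4g (8).

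**Figure D1:**
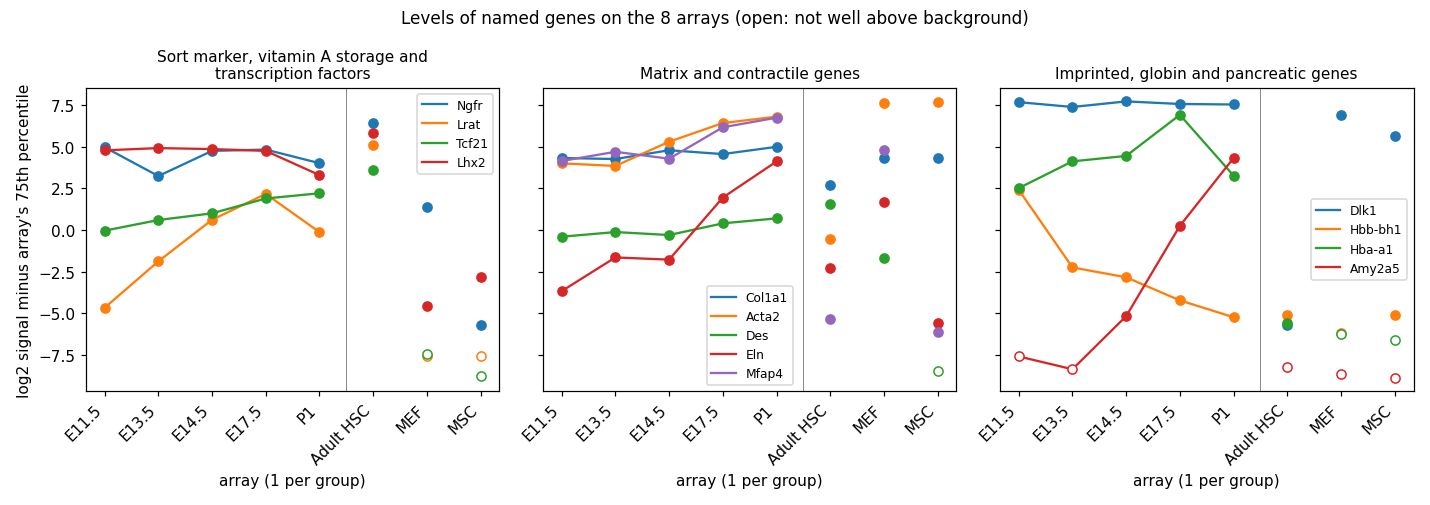
Levels of 13 named genes on the 8 arrays, as log2 signal minus the array's 75th percentile on the vertical axis and 1 array per position on the horizontal axis (open points: not well above background, lines: the 5 stages). Tcf21 goes from -0.04 at E11.5 to 2.20 at P1 and 3.58 in adult HSC, and Dlk1 from 7.54 at P1 to -5.72 in adult HSC.

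The second question was how p75NTR-positive cells change from E11.5 to P1. Tcf21 went from -0.04 at E11.5 through 0.60 at E13.5 and 1.89 at E17.5 to 2.20 at P1, a slope of 0.58 ± 0.07 SE per stage. Ier3 and Atf3, induced early in stress responses, had slopes of 1.08 ± 0.12 SE and 1.03 ± 0.10 SE, and Aldh1a1, which makes retinoic acid, 1.65 ± 0.16 SE. Each of these 4 slopes had a limma adjusted p of 0.0579 and the same direction at each of the 4 steps. That p was the lowest of all genes, so 0 of 15461 genes passed over all genes by limma, with 4347 at an unadjusted p under 0.05. The adjustment gave the same lowest p to other genes as well. The 4 genes were named as list members or, for Tcf21, in advance, and not as the top of all genes. Of 12655 genes above background at all 5 stages, 1420 (11.2%) moved the same way at every step, 411 upward and 1009 downward. The average would be 1.67% over random orders of the arrays, with an unknown spread, so this excess is not a test either.

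Groups of genes passed when adjusted over the list alone. Of 24 myofibroblast and fibrosis genes, 17 rose, among them Acta2 (slope 0.82 ± 0.13 SE, reaching 6.81 at P1). Of 11 portal fibroblast markers, 9 rose, such as Eln, elastin (1.92 ± 0.26 SE), and of 16 basement membrane genes 9 rose, such as Col4a1 and Col4a2 (0.99 each). All 12 immediate early and stress genes rose, with a median slope of 0.79, and so did all 11 interferon response genes, with a median of 1.06 (Ifit3 1.59 ± 0.31 SE). The interferon median slope ran from 0.22 to 1.31 over the alternatives. Of 10 smooth muscle and pericyte markers 6 rose (Myh11 1.45 ± 0.19 SE), of 11 leukocyte and Kupffer cell markers 6 (Lyz1 0.97 ± 0.08 SE, below background at E11.5; the list's median changed sign with normexp), and of 18 stellate cell markers 3: Vipr1, a peptide hormone receptor (1.33 ± 0.20 SE), Cygb, cytoglobin (0.93 ± 0.18 SE) and Gfap, which was above background at E17.5 only. Lrat went from -4.68 at E11.5 to 2.16 at E17.5 and -0.13 at P1 (limma adjusted p = 0.161 over all genes), and Ngfr (slope -0.03 ± 0.22 SE), Des (0.27 ± 0.08 SE) and Col1a1 (0.16 ± 0.07 SE) did not pass over all genes. Of 22 cell cycle genes, 20 fell, such as Aurka, a mitotic kinase, from 3.47 to -0.08, and Ccnb1, cyclin B, from 4.19 to 1.17. Of 24 Hox genes, 8 fell, such as Hoxc5, from -0.40 to -5.08, and Hoxc4, from 2.16 to -1.16.

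Other lists gave fewer calls adjusted over the list alone: retinoid handling 3 up (Aldh1a1, Aldh1a3, Adh1) and 2 down (Crabp1, Stra6) of 19, and hepatic mesenchyme factors 3 up (Tcf21, Heyl, Irf1) and 3 down (Nr2f1, Gata4, Hlx) of 16. Bone and adipose lineage markers gave 3 up (Lpl, Nt5e, Acan) and 1 down (Col2a1) of 8. Niche factors, endothelial and neural crest markers gave 1 up each (Il6, Eng, S100b) of 14, 15 and 8. Imprinted growth genes gave 1 down of 10 (Cdkn1c), and skin, limb and skeletal factors (17), hepatocyte (14), erythroid (14) and mesothelial markers (9) gave 0 by limma, with 4, 1, 1 and 2 at an unadjusted p under 0.05. Crabp1 and Stra6, a retinoic acid binder and a retinol transporter, had slopes of -1.68 ± 0.39 SE and -1.80 ± 0.41 SE, and were below background at P1 (Stra6 also at E17.5). At E11.5, Nt5e, Acan, Il6 and S100b were below background. Alb, a hepatocyte marker, stood at -2.03, 5.55, 7.19, 4.18 and 2.77 on the 5 arrays, and the embryonic globin Hbb-bh1 at 2.41 at E11.5 and -5.25 at P1. By camera with its preset correlation 10 of 21 lists shifted (stellate, fibrosis, basement membrane, immediate early, interferon, leukocyte, portal fibroblast and smooth muscle upward, Hox and cell cycle downward), and with an estimated correlation 0 (lowest adjusted p = 0.358 with an estimated correlation). The gene count became 103 after quantile normalization and 677 among genes above background on every array. It became 1152 with a mean-variance trend and a robust prior together, a setting chosen after the data were seen. On slide 1 alone, which leaves the 4 fetal arrays, 0 genes passed by limma and 15 lists shifted, and the P1 array is the only stage on slide 2.

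The third comparison set the last stage against the first. No test applies with 1 array on each side, and the slides differ, so stage and slide cannot be told apart. The E11.5 array also had the lowest spike-in slope, 0.849 against 0.922 to 0.933 on the others. No correction was made for it, and its effect on these folds was not tested. On the P1 array 1445 genes were at least 4-fold higher than on the E11.5 array and 628 lower, of 14895 compared, or 1099 and 491 with levels below background set at their bound. The median of all genes was -0.09, and -0.27 with median normalization. Among the genes that were higher were Ltbp2, a latent TGF-beta binding protein, 491-fold, Tnxb, tenascin-X, 256-fold, Eln 222-fold, Ogn, osteoglycin, 174-fold, Fndc1 149-fold and Thbs2, thrombospondin, at least 306-fold. Others were the complement genes C2, 448-fold, and C4b, 244-fold, and Ifi27l2a, an interferon-induced gene, 167-fold. Probes of a gene differed in size for Fndc1 (log2 differences from 1.69 to 7.22), Vipr1 (1.20 to 4.63), Lin28b (-6.15 to -3.84) and Amy2a5 (7.62 to 11.93). Pancreatic enzymes stood there too: Amy2a5, pancreatic amylase, at least 820-fold by the probe taken, the trypsin-like Try5 at least 459-fold and Gm5771 at least 446-fold, Amy1 208-fold and Ctrb1, chymotrypsinogen, 160-fold. On the lower side, the embryonic globins Hbb-bh1, Hbb-y and Hba-x were 202-fold, 88.7-fold and at least 40.7-fold lower, and Hmga2 and Lin28b, which mark fetal growth, 127-fold and at least 67.1-fold lower. Heart muscle genes were lower as well, Myl2 90.5-fold, Nppa 63.1-fold, Myh7 59.4-fold and the troponin Tnni1 66.9-fold, as were Dgkk 89.9-fold, Dkk1, a Wnt inhibitor, 83.7-fold, Asic4 83.4-fold and Grin2c at least 71.2-fold.

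By list, members at least 2-fold apart counted as higher or lower, and the medians were set beside 10000 random lists of like expression. Portal fibroblast markers had a median of 6.30 on the log2 scale (9 of 11 higher, such as Thy1, 147-fold, and Clec3b, 114-fold), above the central 95% of random lists (-0.67 to 0.62). The interferon list had a median of 4.34 (3.11 at its bounds, 8 of 11 higher, Ifit3 70.6-fold, Cxcl10 51.5-fold). Over the alternatives that median ran from 0.75 to 4.86, so its size is not firm. The immediate early and stress list had a median of 2.85 (12 of 12, Zfp36 28.7-fold, Junb 22.4-fold), and the fibrosis list 2.03 (16 of 24, Spp1 at least 44.1-fold, Acta2 by 2.81 and Col1a1 by 0.67). The smooth muscle list (2.22, 7 of 10, Myh11 40.4-fold), the basement membrane list (1.26, 12 of 16, Lama2 22.0-fold) and the bone and adipose list (2.65, 5 higher and 1 lower of 8, Col2a1 46.5-fold lower) also lay above. Stellate markers had a median of 0.60 (5 of 17 higher, Vipr1 24.7-fold, Lrat 23.4-fold, Cygb 11.3-fold), with Ngfr at -0.96 on the log2 scale and Des 2.15-fold higher. Retinoid handling genes (0.47, 7 higher and 4 lower of 19) held Aldh1a1, 80.5-fold higher, and Crabp1 and Stra6, at least 62.8-fold and at least 55.1-fold lower. All 22 cell cycle genes were lower (median -1.76, Aurka 11.7-fold), and so were 15 of 23 Hox genes (-1.23, Hoxc5 25.7-fold) and 8 of 15 endothelial markers (-1.40, 3 higher, Oit3 24.3-fold lower, Stab2 12.6-fold lower). Hepatic mesenchyme factors had a median of -0.30 (4 higher, 3 lower of 16, Tcf21 4.75-fold higher, Nr2f1 4.36-fold lower), imprinted genes -0.33 (2 lower of 10), skin, limb and skeletal factors -0.45 (4 and 4 of 17), neural crest markers -0.62 (1 higher, 4 lower of 8) and mesothelial markers -0.99 (1 higher, 4 lower of 8). Niche factors had a median of 0.63 (5 higher, 3 lower of 12, Il6 at least 70.1-fold higher), which changed sign among genes above background on both arrays. Among markers of other cells, 12 of 14 hepatocyte markers were higher (median 2.83, Ahsg, fetuin, at least 666-fold, Alb 27.8-fold), 6 of 11 leukocyte markers were higher (1.69, or 1.06 at their bounds, which lies inside the central 95% of random lists, Marco at least 10.8-fold), and erythroid markers had a median of 0.54 with 2 higher and 4 lower of 13. With normexp correction 590 genes were 4-fold apart, and 1116 among genes above background on both arrays, and 16 of the 21 lists lay outside the central 95% of random lists. The random lists draw genes independently, while members of a list can move together. That central 95% may thus be too narrow, and a place outside it is no test.

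**Figure D2:**
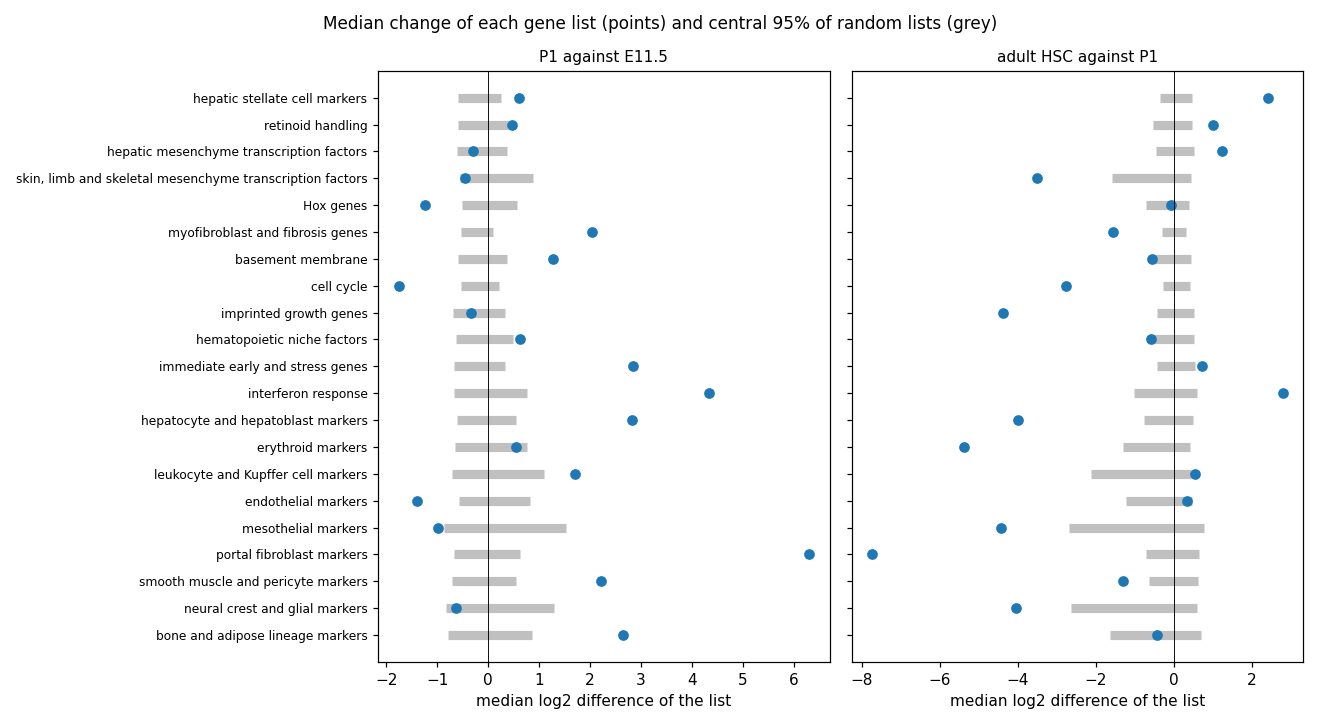
Median log2 difference of each of the 21 gene lists (points, horizontal axis) for the P1 array against the E11.5 array and for the adult HSC array against the P1 array, with the central 95% of random lists of like expression in grey. Genes of the random lists were drawn independently, so the grey range may be too narrow for genes that move together. Portal fibroblast markers lie at 6.30 in the first comparison and at -7.73 in the second, and the interferon response list at 4.34 and 2.80.

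The fourth comparison set adult HSC against P1 cells, both on slide 2. Sort and age differ together, as the adult cells were sorted by vitamin A and the newborn cells by p75NTR, and no test applies. On the adult array 778 genes were at least 4-fold higher and 2369 lower, of 14902 compared (687 and 1868 at the bounds). The share higher was 24.7%, and it was 48.5% with median normalization, which moved the median of all genes from -0.06 to 0.73. Imprinted growth genes were all lower (10 of 10, median -4.37): Dlk1, a Notch-like factor of fetal cells, 9806-fold, Meg3, a long noncoding RNA, 244-fold, Igf2 222-fold and Cdkn1c, a cell cycle inhibitor, 30.0-fold. Among the other genes that were lower were Mfap4, a microfibril protein, 4386-fold, Ltbp2 1106-fold, Fbn2, fibrillin, 724-fold, Cnn1, calponin, at least 1623-fold, Actg2, an enteric actin, at least 3621-fold, Mgp, matrix Gla protein, at least 1589-fold, and Acta2 161-fold. Others on that side were Thy1 868-fold, Fxyd6 792-fold, Lrrc17 427-fold, Lsp1 358-fold, Cpe, carboxypeptidase E, at least 2304-fold, Amy2a5 at least 1231-fold by the probe taken, and the globins Hba-a2 and Hba-a1, 1097-fold and 468-fold. The higher side held Fcna, ficolin A (545-fold), Disp2 (459-fold), the chemokine Cxcl14 (at least 1673-fold), Sucnr1, the succinate receptor (147-fold), Naip2 (137-fold), Ptger2, a prostaglandin receptor (135-fold), and the MHC class I gene H2-Q8 (124-fold). It also held Nlrc5, which drives MHC class I genes (113-fold), Pde8b (109-fold), Gvin1 (103-fold), Slco4a1 (96.8-fold), Mlph (at least 102-fold), Mup19 (at least 96.8-fold), Tmem273 (at least 84.5-fold) and D5Ertd605e (at least 81.1-fold). Probes of a gene differed in size for Nlrc5 (log2 differences from 1.83 to 6.82), Cpe (-13.28 to -6.01), Cd34 (-8.32 to -5.11), Meg3 (-8.29 to -4.57) and Amy2a5 (-12.56 to -8.18).

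By list, stellate markers had a median of 2.41 (13 of 18 at least 2-fold higher, 0 lower), with Lrat 38.0-fold, Bmp5 16.1-fold and Vipr1 14.3-fold higher, Ngfr by 2.41 and Des by 0.89 on the log2 scale. All 11 interferon response genes were higher (2.80, Rsad2 12.4-fold), as were 9 of 17 retinoid handling genes (1.01, 4 lower, among them Aldh1a2 at least 65.1-fold and Rbp4 54.3-fold) and 9 of 16 hepatic mesenchyme factors (1.23, Lhx2 5.67-fold and Tcf21 by 1.37 on the log2 scale, with Wt1, a mesothelial and stellate factor, 72.2-fold lower). Immediate early and stress genes had a median of 0.72 (5 higher, 1 lower of 12, Dusp1 4.52-fold). All 11 portal fibroblast markers were lower (-7.73, Pi16 at least 363-fold, Cd34 319-fold), with 10 of 15 skin, limb and skeletal factors (-3.51, Meox2 at least 114-fold), 19 of 22 cell cycle genes (-2.76, Birc5 24.3-fold), 15 of 24 fibrosis genes (-1.55, 2 higher, Lox at least 144-fold, Col1a1 by -2.27 on the log2 scale), 7 of 8 neural crest markers (-4.05, S100b at least 53.0-fold) and 5 of 6 mesothelial markers (-4.44, Krt19 at least 42.1-fold). Smooth muscle markers split (-1.30, 4 higher, 5 lower of 10, Rgs5 27.7-fold higher, Myocd at least 93.1-fold lower), with a median of 1.04 among genes above background on both arrays. Basement membrane genes (-0.56, 2 higher, 4 lower of 16, Lama1 8.68-fold higher, Col4a5 at least 93.3-fold lower), niche factors (-0.59, 5 and 5 of 13, Ptn at least 944-fold lower) and bone and adipose markers (-0.42, 3 and 3 of 8, Alpl 39.8-fold higher) changed the sign of their median with median normalization, the niche factors also with no filter on dim probes, and Hox genes (-0.08, 4 higher, 3 lower of 20, Hoxc4 14.4-fold lower) with that, quantile normalization, normexp and the mean of all probes. Of the lists of other cells, 13 of 14 hepatocyte markers were lower and 1 higher (-4.01, Afp at least 423-fold lower, Ahsg 58.4-fold lower), 9 of 13 erythroid markers were lower (-5.38, or -4.24 at their bounds, Hbb-bt at least 519-fold), endothelial markers had a median of 0.35 (5 higher, 3 lower of 14, Plvap 16.6-fold higher) and leukocyte markers of 0.54 (4 higher, 2 lower of 12, Cd74 10.7-fold higher). With normexp 1036 genes were 4-fold apart, and 1490 among genes above background on both arrays, and 17 of the 21 lists lay outside the central 95% of random lists. That range may again be too narrow for genes that move together.

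The last comparison clustered the 8 arrays by Euclidean distance with centroid linkage, the clustering named in the deposited description. The E13.5 and E14.5 arrays joined first and the E17.5 and P1 arrays second, although the latter pair lies on different slides. These 4 then joined, followed by E11.5, MEF, adult HSC and MSC. The root mean square difference was 0.83 between E13.5 and E14.5 and 0.92 between E17.5 and P1 on the log2 scale over 29410 probes, and 1.39 between E11.5 and P1. Adult HSC lay nearest to E17.5 (1.65) and P1 (1.83), and farther from the MEF (2.14) and MSC (2.42) arrays. The mean distance from the 5 stages was 0.32 greater for adult HSC than for MEF, a value of 0.25 with no filter on dim probes and 0.08 with normexp. By 1 minus Pearson correlation with average linkage, E11.5 joined the E13.5 and E14.5 pair before the other stages did, and the later joins came in the same order.

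**Figure D3:**
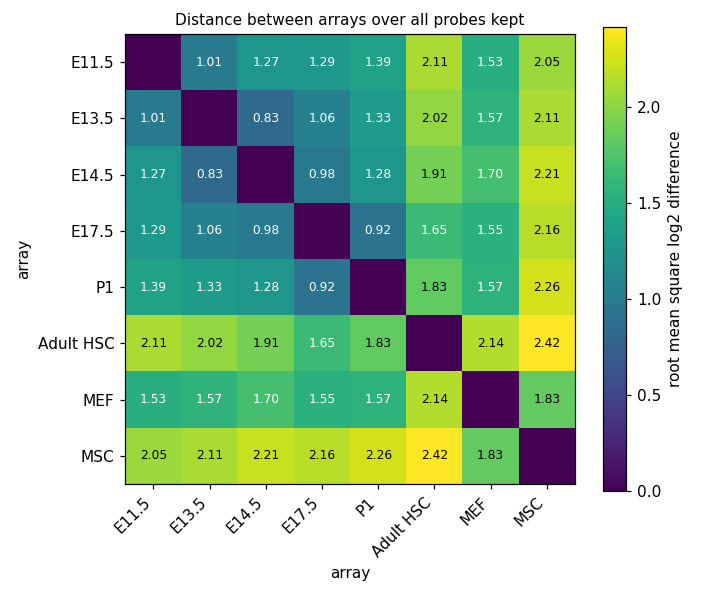
Root mean square log2 difference between each pair of the 8 arrays over 29410 probes, with arrays on both axes and the value as color and number. The smallest value is 0.83, between E13.5 and E14.5, and the largest is 2.42, between adult HSC and MSC.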

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

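No test in this part was chosen after the result was seen. Of the probes with no gene name, which no comparison in the report uses, 29 were well above background on each of the 6 liver-derived arrays and on neither the MEF nor the MSC array. They were singled out because they carry a signal in data outside the named genes, with the MEF and MSC arrays as the comparison. A gene for these probes is not given in the sources used here, and no explanation was tested.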

How the results depend on the processing

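Tests chosen after the result was seen were slide 2 alone, the mean-variance trend with a robust prior, the bounds for pairs and the leave-outs of the lists. Of the 120 alternatives to counts and to the clustering value, 93 were labelled the same and 27 moved. A count was labelled the same within 1.5 times. The clustering value was labelled the same within the SD of the distances from MEF to the stages. With the Pearson correlation, which has another unit, only its sign was compared. The pair counts could not change with no filter, as the brighter array still had to be above background. Of single values, 1643 stayed the same, 145 lost and 33 gained a call and 4 reversed. Another 2536 were labelled as moved. Any pair difference or median got that label unless it reversed, however small its change, so 2536 does not measure instability. In all alternatives 219 of 221 pair values and 69 of 84 list medians kept their sign. These alternatives mostly reprocess the same arrays, and many pair values were named for their large size. A kept sign therefore says nothing about what a replicate array would show.

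The cause was not tested unless stated. At 2-fold the pair counts were 5092 (P1 against E11.5) and 5695 (adult HSC against P1), and at 8-fold 972 and 1935, by construction of the threshold. With normexp they were 590 and 1036, and among genes above background on both arrays 1116 and 1490, where fewer genes are compared. The liver comparison gave 51 genes with normexp, 157 among genes above background on all arrays, 524 with only the 5 p75NTR-positive arrays as liver, 74 with slide as a block, and 0 within slide 2 (limma, 1446 at an unadjusted p under 0.05), where 2 arrays stand on each side. Leaving out 1 array gave 82 (without E17.5) to 1277 (without MEF) genes, with the lone array of a side assumed to vary like the others. The slope gave 103 genes with quantile normalization, 677 among genes above background on all arrays and 1152 with the mean-variance trend and robust prior together. With an estimated correlation 0 lists shifted in the liver comparison and 0 over the stages, and 9 lists shifted in the liver comparison among genes above background on all arrays. The clustering value was 0.247 with no filter and 0.0760 with normexp.

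A pair value or list median counts as reversed when it changed sign and its size, or for a gene dim on one side its bound, was at least 1 on the log2 scale. Of the 15 list medians that changed sign, 13 were smaller than that: basement membrane, bone and adipose, niche and Hox (adult HSC against P1), niche (P1 against E11.5), niche, imprinted, leukocyte and neural crest (stages), and bone and adipose, interferon, leukocyte and neural crest (liver comparison). The reversed values were Col4a4 in adult HSC against P1 (-0.92 with the mean of all probes), the Hox median of the liver comparison (0.064 with normexp, 0.38 among genes above background on all arrays) and the smooth muscle median in adult HSC against P1 (1.04 among genes above background on both). No paired analysis was possible because the labels give no replicate numbers and each group has 1 array. Signal over background limits depth: 11305 of 20062 genes were above background on all arrays.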

Other observations

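Tests chosen after the result was seen were the 3 on portal fibroblast and stellate genes between E17.5 and P1; the others here were fixed before their results. Between the cultured and marrow cells, 485 genes were at least 4-fold higher and 2387 lower on the MSC than on the MEF array. Between adjacent stages 801, 740, 1040 and 744 genes were at least 4-fold apart, the last of these, from E17.5 to P1, with 566 higher and 178 lower.

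Of 28 ways to split the 8 arrays into 6 and 2, 2, the real one included, gave at least as many genes as the liver comparison. Chance is therefore not excluded for its count of 259. The highest other split gave 435 genes and set the adult HSC and MSC arrays, both on slide 2, against the rest. The rest held the P1 and MEF arrays of slide 2, so slide does not define that split. With slide as a block the liver comparison gave 74 genes. That blocked difference is the one within slide 2, as slide 1 holds no other cells, and it rests on arrays that also gave the 259 genes (Lhx2 8.25 against 8.44). Of 60 orders of the 5 stage arrays, 1, the real one, gave as many genes with a slope at an unadjusted p under 0.05 (4347, highest other 3472). That argues against a random order for that count, though 1 of 60 is the smallest share this test can give. The highest other order only swaps E17.5 and P1, and slide and stage stay joined at P1.

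Digestive enzymes of the pancreas were present on the P1 array, and carry-over of pancreatic tissue may be their source. In a list of 20 further acinar genes on the array, fixed before their values were seen, 18 were well above background at P1, and the median lay 6.46 above adult HSC on the log2 scale. The highest signals, which are not comparable as abundance between probes, were those of Try4 (2.78), Pnliprp1 (2.55) and Cpa1 (2.39), and the list's median was 0.38 at P1 and -4.66 at E17.5, where 11 of the 20 were above background. Some are not particular to P1: Spink1 (-0.65) stood at 4.12 at E14.5, Pnliprp1 at 1.62 at E14.5, and Pnlip was below background at P1 and at -3.19 at E13.5. The tables argue against an effect of slide 2, since the median gap to the highest other array of that slide was 5.07. The p75NTR gate should remove acinar cells, but how well it did so was not measured, and no biological explanation was tested.

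Heart muscle genes stood on the E11.5 array, where carry-over of heart tissue may be their source. Of 13 further cardiac genes fixed before their values were seen, 12 were above background there and 12 were higher than at E14.5 (all but Tnnc1, with 9 above background at E14.5), with a median gap of 3.53 on the log2 scale. The highest signals were those of Actc1 (3.14), Myl4 (2.46) and Myl3 (2.33), and Tnnt2 stood at 0.11 and, at P1, at 3.04. Some of the genes are not particular to that array: Actc1 (4.18), Myl4 (4.30), Tnnt2, Ttn and Tnnc1 were higher on the MEF array, and Nkx2-5 on the MSC array (3.13 against 0.04). The p75NTR gate should remove heart muscle cells, but how well it did so was not measured, and no biological explanation was tested.

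From E17.5 to P1 portal fibroblast markers were higher (11 of 11, median 1.53). Of 125 genes picked as high at E17.5 and in adult HSC against MEF and MSC, without the P1 array, 101 were lower (median -0.87). Picking genes for a high E17.5 value favors a lower value at P1, so this count is no independent evidence. The 125 also hold the endothelial markers Plvap and Stab2 and the hepatocyte marker Trf. The fixed list of stellate markers had a median of -0.81, with 3 of 18 higher at P1. A smaller share of stellate cells may add to these differences. With the mix of the other cells unchanged, a smaller share would raise markers of every other cell type. The erythroid median was -2.83 against 1.63 for mesothelial and 1.12 for neural crest markers, which argues against that simple case only. The mix of the other cells may change too, so a smaller stellate share is not excluded. An effect of slide 2 cannot be told apart, because P1 is the only p75NTR-sorted array there; portal markers on its adult HSC array lay at -6.51 relative to E17.5, but those cells differ in sort and age. The tables argue against the scaling, as the portal median after quantile normalization was 1.63. Age, which the design names, stays open and untested, and a change in the portal fibroblasts of the sort does too.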
